A study of Homo sapiens with 24 samples.

How the data were processed

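RNA was sequenced from 24 samples of THP-1 cells, a human monocytic leukaemia line. Per the labels' protocols, the cells were turned into macrophages by 72 hours of phorbol ester (PMA) at 20 nM and were then left resting (M0), given 1 ug/ml LPS with 100 ng/ml interferon gamma (M1), or given 100 ng/ml IL-4 (M2). The length of the M1 and M2 treatments is not given in the sources used here. The knockdown cells (CES1KD) carried a stable lentiviral short-hairpin RNA against CES1, and the comparison cells are named WT in the sample labels and control in the series text. Whether the WT cells carried a control vector is not given in the sources used here, so an effect of the vector cannot be told apart from one of CES1 loss. Each of the 6 groups of genotype and state had 4 libraries. The labels' protocols give an RNA integrity number (RIN) above 4. The labels do not say that replicates are separate cultures, so the p-values measure only the spread between these samples.

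The deposited table held FPKM (fragments per kilobase of gene length, scaled by library size) for 58735 genes, with the gene length, coordinates and biotype of each. CASAVA, HISAT2 and DESeq are named in the submitters' processing notes. Their versions and roles, the aligner settings, the genome build and the annotation are not given in the sources used here. Each FPKM value times its gene length was a whole multiple of 1 step per library (tolerance 1e-06 of a step, 100% of the genes in each library), which gave back the fragments behind every value. The libraries held 14881563 to 26671681 fragments on genes. The step also showed that the authors had divided the FPKM values by an adjusted library size, not by the total, by a method that the notes do not describe. The adjusted size was 0.87 to 0.946 of the total in M1 libraries and 1.01 to 1.14 of it in M0 and M2 libraries. A level in an M1 library thus depends on that adjustment, and alternatives with other scalings were run for it. Coordinates are given as in the deposited table.

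Genes with FPKM of at least 1 in at least 4 of the 24 libraries were kept, 13242 of the 58735, of which 10946 were protein-coding. A value of 1 was added before log2, so differences of genes near 0 depend on that value and understate the ratio. One linear model with a mean for each of the 6 groups was fitted to all 24 libraries with limma 3.58.1 (lmFit, contrasts.fit and eBayes with an intensity trend) in R 4.3.3. Tests were two-sided with Benjamini-Hochberg adjustment over the genes kept within a comparison, and genes with adjusted p under 0.05 were called. The comparisons were CES1KD against WT in M0, M1 and M2, the differences of the M1 and of the M2 knockdown effect from that in M0, and M1 and M2 against M0 within each line. The knockdown comparisons in the 3 states share no libraries, while the M1 and M2 comparisons within a line share its M0 libraries. Changes are given as log2 differences with the standard error (SE) of the fit, and levels as mean FPKM with the standard deviation (SD) over 4 libraries.

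The model, its tests, 35 gene lists and the rule for named genes were chosen before the data were examined. The rule took CES1 and, for each knockdown comparison, the 10 highest and 10 lowest protein-coding genes that passed the test, whose libraries did not overlap between the groups and whose mean was at least 2 FPKM in the higher group. It took 10 genes in each direction for effects common to the 3 states, ranked by the smallest of the 3 effects. It took 8 in each direction for each difference of effects, 5 in each direction for each WT stimulation, and up to 4 members of each list per comparison by p. Genes on chromosome Y and XIST were left out. A gene named under 1 comparison is also given its values in others. The results of 2 genes that the rule took are not reported here.

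The 35 lists covered lipid ester hydrolases, cholesterol synthesis and uptake, LXR targets, PPARG targets and fatty acid handling, scavenger receptors, lysosome, eicosanoids, retinoids, oxysterols and bile acids, inflammatory cytokines and NF-kB targets, inflammatory chemokines, the type I interferon response, and the interferon gamma response with MHC class I. They also covered MHC class II, the IL-4 response, receptors and signalling for LPS, interferon gamma and IL-4, the unfolded protein and integrated stress response, NRF2 targets, metallothioneins, glycolysis and hypoxia, nuclear and mitochondrial genes of oxidative phosphorylation, cell cycle, progenitor and granule genes, monocyte markers, macrophage differentiation markers, matrix genes with proteases and inhibitors, complement and Fc receptors, heat shock, immediate early genes, replication-dependent histones, and markers of fibroblasts, epithelium, lymphocytes and erythroid cells. The 31 lists with at least 5 members among the genes kept were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, in 7 comparisons. Each test was repeated with a correlation estimated from the data. For CES1 an exact permutation test of the 4 against 4 libraries was added, and the share of its fragments left was given a 95% interval from the exact test of a ratio of Poisson rates.

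The method was tested on simulated data with 13242 genes. For the knockdown in M0 it recovered 83.3% of 66 genes changed by 0.5 on the log2 scale, 97% of 67 changed by 1 and 100% of 67 changed by 2, with 6 other genes called. For the difference between M1 and M0 it recovered 62.1%, 92.5% and 100% of the same genes, with 12 others called. In the simulated M1 and M2 comparisons, where nothing was changed, 0 genes were called. It called 5 of 5 simulated lists of 20 genes shifted by 0.5 and 0 others, and found 120 of the 120 genes of a simulated shifted chromosome block. Changed genes and list members were drawn from those with a WT M0 mean of at least 2 as log2 of FPKM plus 1. Noise was drawn independently for each gene, while the correlation estimated within real lists reached 0.718 (immediate early genes). The simulated lists therefore cannot show how the list test behaves when members are correlated.

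Alternatives covered the value added before log2, the filter, rescaling to TPM, upper-quartile and quantile scaling, robust and weighted fits, voom on the fragments, a replicate block, fits on only the groups compared, and leaving out each library. Chosen after the data were seen were fits to protein-coding genes only, without genes of 4 chromosome blocks, and with each library's trends with GC content and length removed. GC content came from GENCODE 29 transcripts, matched by gene ID. For 1 of the tests of explanations, a form other than the planned one was run first, and both are given where the test is described. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.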

Results

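CES1 encodes carboxylesterase 1, a serine hydrolase of the endoplasmic reticulum that cleaves esters of lipids and drugs. The series asks what its loss does in THP-1 macrophages that are resting (M0), stimulated with LPS and interferon gamma (M1) or stimulated with IL-4 (M2). RNA sequencing profiled 12 libraries of knockdown cells (CES1KD) and 12 of control cells (WT), 4 in each of the 6 groups of genotype and state. The libraries held 14881563 to 26671681 fragments on genes, with 20275 to 25065 genes above 0. Mitochondrial genes took 1.01 to 2.8% of the fragments of a library and the 10 most abundant genes 5.7 to 7.55%. Pairs of libraries of the same group correlated across genes at r between 0.951 and 0.991 on the log2 scale. The leading principal component carried 46.2% of the variance and the next 23%.

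CES1 lies on chromosome 16, minus strand, from 55802851 to 55833337 in the coordinates of the deposited table. Its level was 7.13 ± 0.678 FPKM in WT M0, 4.63 ± 0.759 in WT M1 and 6.32 ± 0.61 in WT M2 (SD, n = 4 each). In knockdown cells it was 0.0809 ± 0.0542 in M0, 0.0286 ± 0.0379 in M1 and 0.0505 ± 0.0525 in M2. The mean was 98.9% lower in M0, 99.4% lower in M1 and 99.2% lower in M2, where the series text states a reduction of at least 85%. WT libraries lay between 4.04 and 7.78 FPKM, and CES1KD libraries between 0 and 0.124. Among the CES1KD libraries, 4 had no CES1 fragment, which allows up to 0.0407 to 0.0755 FPKM. Summed over 4 libraries, the fragments were 1575 in WT and 18 in CES1KD cells in M0, 978 and 7 in M1, and 1394 and 12 in M2. The share left was 1.06% in M0 (95% interval 0.626 to 1.68), 0.682% in M1 (0.273 to 1.41) and 0.742% in M2 (0.383 to 1.3), and the intervals cover counting error only. The log2 difference was -2.91 in M0, -2.44 in M1 and -2.80 in M2 (SE 0.08 each), with adjusted p = 1.18e-17, 3.26e-16 and 3.99e-17. An exact two-sided permutation test of 4 against 4 gave p = 0.0286 in each state, the smallest it can give.

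**Figure D1:**
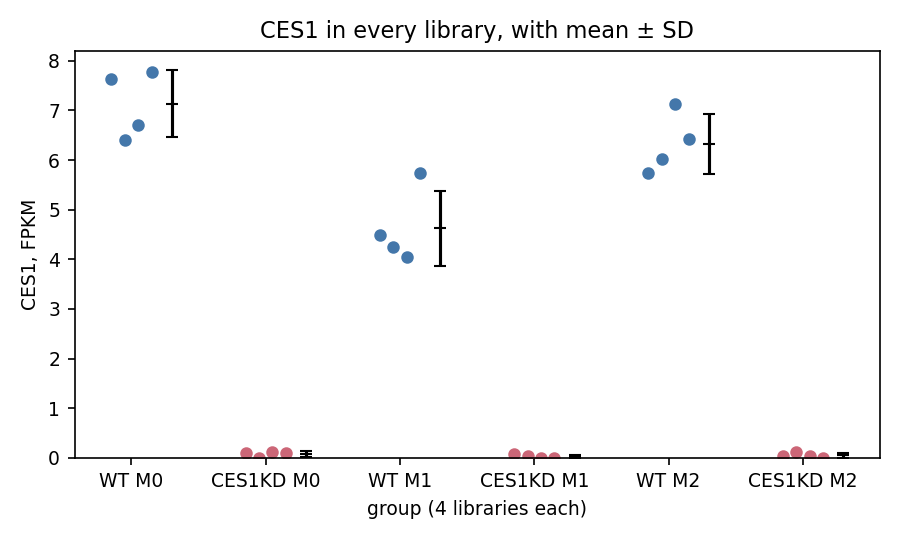
CES1 level in FPKM (vertical axis) in each of the 24 libraries by group, with the mean and SD of the 4 libraries beside the points. WT libraries lie between 4.04 and 7.78 FPKM and CES1KD libraries between 0 and 0.124.

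In resting cells, genes of the interferon response, inflammatory mediators and matrix genes were higher in the knockdown cells, and genes of granules and monocytes were lower. IFIT1, an antiviral protein induced by interferon, went from 1.91 ± 0.451 to 69.7 ± 7.26 FPKM (SD, n = 4 each), a log2 difference of 4.61 ± 0.11 (SE). MMP9, a gelatinase that degrades matrix, went from 59.4 ± 4.5 to 810 ± 60.5 FPKM, and CXCL8, a chemokine that attracts neutrophils, from 11.1 ± 1.02 to 190 ± 20.3. CD9, a tetraspanin of the cell surface, went from 41 ± 0.893 to 0.54 ± 0.0276 FPKM, a log2 difference of -4.77 ± 0.05. CTSG and PRTN3, serine proteases of azurophil granules, went from 29.5 ± 2.2 to 0.506 ± 0.421 and from 72.3 ± 1.34 to 3.62 ± 0.412 FPKM.

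All 26 of the type I interferon response genes rose in M0, with a median log2 difference of 3.0 (camera adjusted p = 5.83e-25). Among them MX1, a GTPase that blocks viruses, went from 0.43 ± 0.0331 to 23 ± 2.37 FPKM, and ISG15, a ubiquitin-like protein, from 25.2 ± 3.73 to 384 ± 41.3. RSAD2 (viperin) rose by 4.05 and OASL by 3.56 on the log2 scale. SIGLEC1, a sialic acid receptor of macrophages that interferon induces, rose by 3.97. Of the 16 inflammatory chemokines, 12 rose and 3 fell (median 1.13, adjusted p = 0.000257). CXCL10, a chemokine that attracts T cells, went from 0.73 ± 0.351 to 37.6 ± 6.35 FPKM, and CCL20 rose by 3.25. Of 13 inflammatory cytokines and NF-kB targets, 11 rose and 2 fell (median 1.10, adjusted p = 0.000257), with IL1B at 2.64 and TNFAIP3, an inhibitor of NF-kB signalling, at 1.97. The interferon gamma and MHC class I list had 13 of 21 members higher and 2 lower, among them GBP1 at 1.84 and B2M at 1.47 (median 0.35, adjusted p = 0.000862). That call was lost with the estimated correlation (adjusted p = 0.315 with an estimated correlation). Over the 7 comparisons, 102 of 217 list tests passed at the preset correlation and 53 with the estimated one. The calls printed without a further p held with the estimated correlation, but their p can be far larger there. For the type I interferon list the estimated correlation was 0.334, which gave camera adjusted p = 0.00645 in M0 and 0.00147 for the difference between M1 and M0.

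Of 19 genes of matrix, proteases and inhibitors, 15 rose and 3 fell in M0 (median 0.95, adjusted p = 1.57e-06). FN1 (fibronectin) went from 2.33 ± 0.101 to 74.2 ± 3.34 FPKM, and MMP7 rose by 1.95. Heat shock genes rose in 8 of 10 and fell in 1 (median 0.79, adjusted p = 0.000982), with the chaperones HSPA1B at 2.61 and HSPH1 at 1.53. NRF2 targets, genes of the oxidative stress response, rose in 9 of 13 (median 0.55, adjusted p = 0.00134), with the cystine transporter SLC7A11 at 2.22 and HMOX1 at 1.27. Replication-dependent histones rose in 6 of 7 (median 1.40, adjusted p = 0.000257), HIST1H2AC by 2.34. Immediate early genes rose in 9 of 11 (median 1.37, adjusted p = 1.42e-05), the phosphatase gene DUSP1 by 2.27, and the unfolded protein and integrated stress response in 10 of 16 with 3 lower (median 0.36, adjusted p = 0.0165), SESN2 by 1.93. With the estimated correlation those calls were lost (adjusted p = 0.251 for immediate early genes and adjusted p = 0.319 for the stress response with an estimated correlation).

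Progenitor and granule genes fell in 7 of 8 (median -3.52, adjusted p = 7.64e-08). ELANE fell by 3.94 and AZU1 by 3.72, which lie beside PRTN3 on chromosome 19, and MYB, a transcription factor of blood progenitors, fell by 3.32. PLPPR3, of the same stretch of chromosome 19, fell by 3.90. Monocyte markers fell in 6 of 8 (median -1.35, adjusted p = 0.000257), with the chemokine receptor CCR2 at -2.91 and lysozyme (LYZ) at -1.93. All 5 metallothioneins tested fell (median -1.64, adjusted p = 0.00103), MT1F by 1.96. DHRS9, a retinol dehydrogenase, went from 19.5 ± 1.35 to 0.572 ± 0.15 FPKM. TAC4, a tachykinin precursor, fell by 4.10, RHEX by 3.66 and MLC1 by 3.61. Cell cycle genes were lower in 15 of 23 and higher in 1 (median -0.42, adjusted p = 0.000257), with CCNB1 at -1.15, but that call was lost (adjusted p = 0.147 with an estimated correlation). Nuclear genes of oxidative phosphorylation were lower in 14 of 18 and higher in 2 (median -0.54, adjusted p = 0.000982), and mitochondrially encoded genes in 10 of 13 (median -0.56, adjusted p = 0.0152), with COX7C at -0.95 and MT-CO3 at -0.88. Both calls were lost with the estimated correlation (adjusted p = 0.444 for the nuclear genes and adjusted p = 0.512 for the mitochondrial genes with an estimated correlation).

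Lipid lists passed in neither direction in M0, with members moving both ways. Of 20 other lipid ester hydrolases, 5 rose and 7 fell (median 0.09, adjusted p = 0.847), among them lipoprotein lipase (LPL) at 1.44, CES3 at -1.48 and MGLL at 1.02. Of 23 genes of cholesterol synthesis and uptake, 9 rose and 5 fell (median 0.04, adjusted p = 0.555), with SQLE at 1.20. LXR targets had 3 higher and 3 lower of 11 (adjusted p = 0.905), with the cholesterol exporter ABCA1 at 1.29. PPARG targets and fatty acid handling had 4 higher and 6 lower of 16 (adjusted p = 0.847), with the lipid droplet protein PLIN2 at 1.32 and FABP4, a fatty acid binding protein, at -1.19. Scavenger receptors had 4 higher and 2 lower of 7 (adjusted p = 0.589), CD163 at 2.04. The lysosome list had 7 higher and 7 lower of 21 (adjusted p = 0.905), and eicosanoids 3 higher and 6 lower of 13 (adjusted p = 0.589). Retinoids had 4 higher and 3 lower of 8 (adjusted p = 0.905), and oxysterols and bile acids 1 higher and 2 lower of 7 (adjusted p = 0.555). Macrophage markers had 7 higher and 8 lower of 16 (adjusted p = 0.978), receptors and signalling 11 higher and 5 lower of 22 (adjusted p = 0.181), and glycolysis and hypoxia 12 higher and 3 lower of 23 (adjusted p = 0.0625). Complement and Fc receptors had 2 higher and 7 lower of 14 (adjusted p = 0.259), MHC class II 1 higher and 5 lower of 10 (adjusted p = 0.0847, but adjusted p = 0.0398 with 0.1 added before log2 in place of 1), and the IL-4 list 1 higher and 3 lower of 9 (adjusted p = 0.304). Adjusted over the list alone, the count in M0 was the same as over all genes for each list except 6. It was 11 for PPARG targets (10 over all genes), 17 for receptors (16), 10 for NRF2 targets (9), 17 for glycolysis (15), 17 for nuclear genes of oxidative phosphorylation (16) and 19 for matrix genes (18).

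Markers of other cell types were mostly below the filter, and 1 of 8 fibroblast markers, 2 of 11 lymphocyte markers, 0 of 8 epithelial and 0 of 8 erythroid markers were tested. The fibroblast marker PDGFRA differed by -0.15 in M0 (not called), -1.09 in M1 and -0.48 in M2, TRAC of T cells by 1.08, 0.44 and 0.34, and PAX5 of B cells by 0.09 (not called), -0.97 and -0.41. In M0 7196 of 13242 genes passed the test, 3718 higher and 3478 lower, and 1116 of them differed at least 2-fold. Control and knockdown cells also differed over long chromosome blocks in all 3 states. In M0, genes of chromosome 1 from 145.7 to 157.0 Mb had a median of 0.57. Those of chromosome 5 had 0.58 from 0.2 to 53.7 Mb and -0.47 from 53.9 to 181.3 Mb, and those of chromosome 8 from 0.4 to 41.5 Mb 0.46. Of the genes named here, CCNB1, COX7C, CD14, CD180, DUSP1, LOX, PDLIM4 and PCDHGA12 lie in the lowered block of chromosome 5, ANKH and OSMR in its raised block, and LPL, MSR1 and IDO1 in that of chromosome 8. Without the genes of these blocks 6453 were called in M0, 6845 in M1 and 6194 in M2, alternatives chosen after the data were seen.

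**Figure D2:**
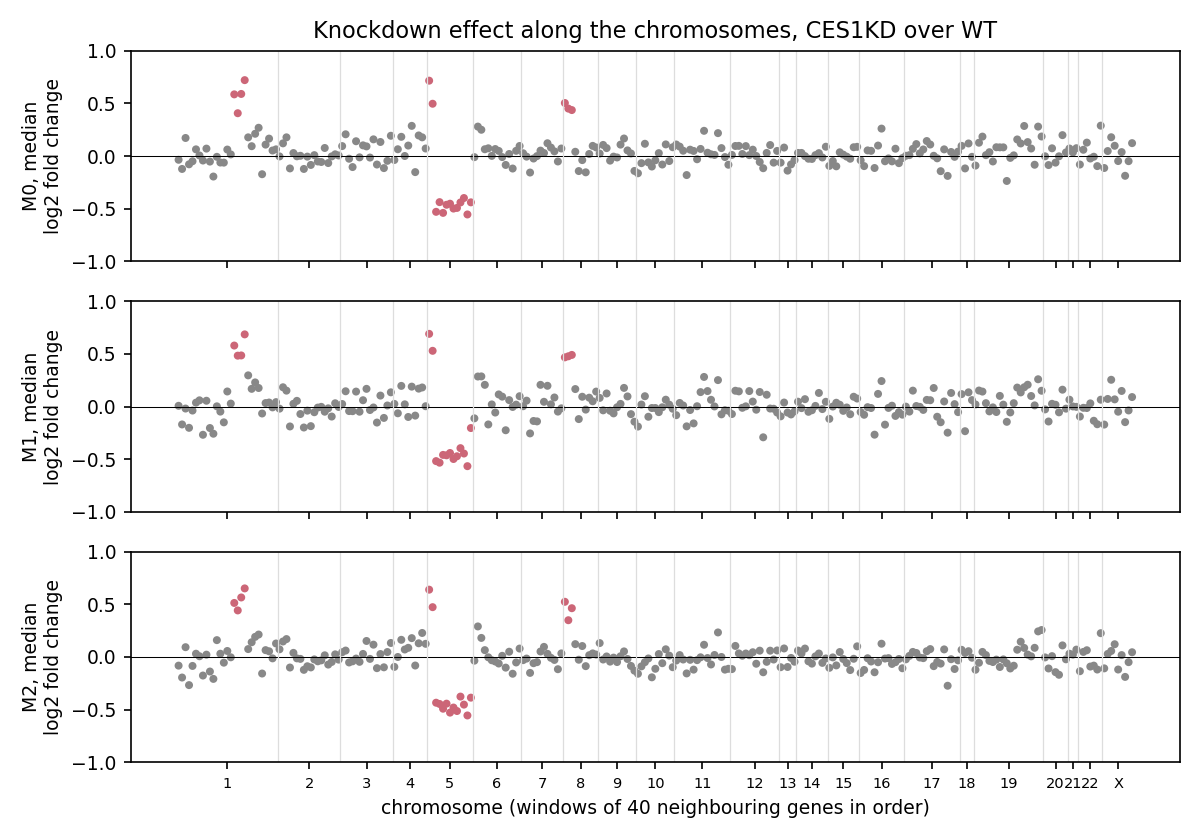
Median log2 difference between CES1KD and WT cells (vertical axis) of windows of neighbouring genes in order along the chromosomes (horizontal axis) in M0, M1 and M2, with the windows of the shifted blocks in red. The blocks lie at 0.57 on chromosome 1, 0.58 and -0.47 on chromosome 5 and 0.46 on chromosome 8 in M0.

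**Figure D3:**
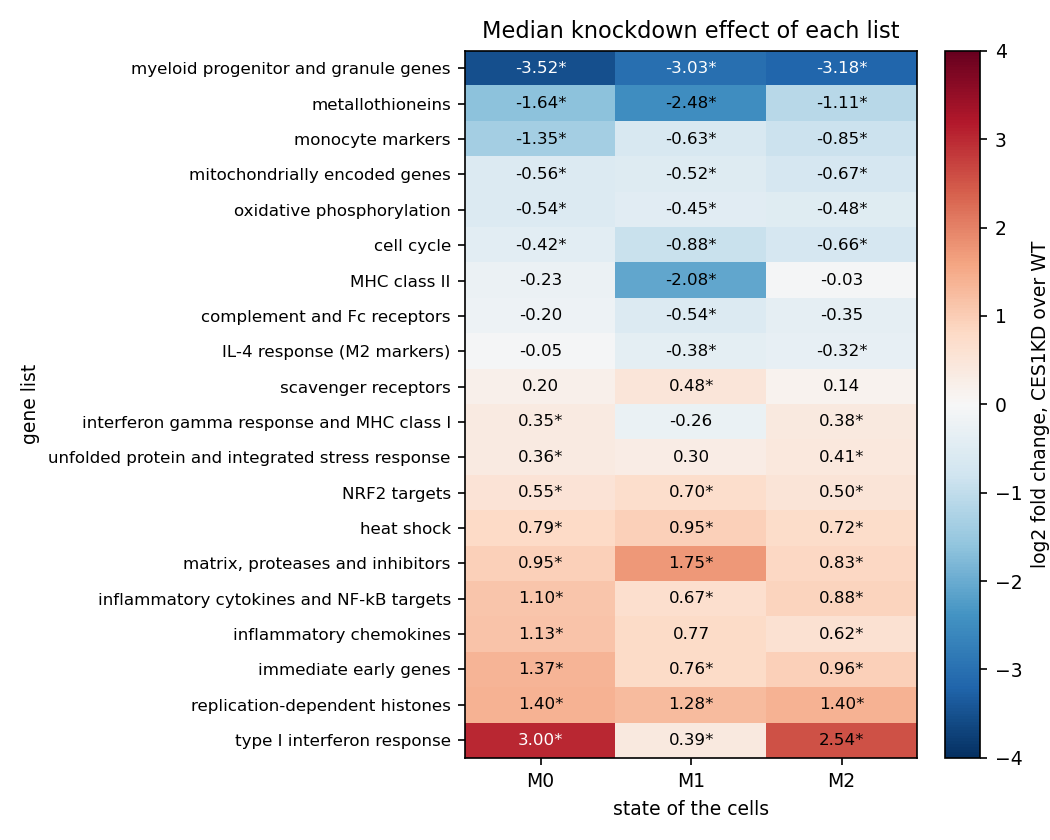
Median log2 difference between CES1KD and WT cells (colour and number) of each gene list called in at least 1 state, by state, with an asterisk where the camera adjusted p was under 0.05 at the preset correlation. The type I interferon response was at 3.0 in M0, 0.39 in M1 and 2.54 in M2, and granule genes at -3.52, -3.03 and -3.18.

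In M1 cells, MHC class II genes and some chemokines were lower in the knockdown cells, while matrix, NRF2 target and heat shock genes were higher. CCL7 and CCL1, chemokines for monocytes and T cells, went from 368 ± 16.3 to 15.8 ± 1.89 FPKM and from 574 ± 49.2 to 27.2 ± 3.17 (SD, n = 4 each). C1QB, a chain of complement C1q, went from 33.2 ± 6.95 to 1.24 ± 0.233 FPKM, and HLA-DRA, the alpha chain of HLA-DR, from 434 ± 28.4 to 59.7 ± 5.48. NR4A3, an orphan nuclear receptor, went from 0.695 ± 0.0794 to 23 ± 1.5 FPKM, a log2 difference of 3.82 ± 0.07 (SE). TGFB3 went from 0.789 ± 0.129 to 16.3 ± 1.51 FPKM, and SLC7A11 from 1.04 ± 0.107 to 18 ± 0.89.

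All 10 MHC class II genes fell in M1 (median -2.08, adjusted p = 2.73e-10), HLA-DPA1 by 3.14 and HLA-DMB by 2.31. The interferon gamma and MHC class I list had 8 members higher and 10 lower of 21 (median -0.26, adjusted p = 0.269), among them the tryptophan-degrading enzyme IDO1 at -2.09 and GBP5 at -1.65. Chemokines had 9 higher and 5 lower of 16 (median 0.77, adjusted p = 0.201), with CXCL9 at -2.88 and CXCL2 at 2.47. Type I interferon genes rose in 19 of 26 and fell in 1 (median 0.39, adjusted p = 0.00103), MX1 by 1.47, and IFI27 fell by 1.20. That call was lost with the estimated correlation (adjusted p = 0.417 with an estimated correlation). Among these genes IFIT1 was 140 ± 7.71 FPKM in WT and 249 ± 15.3 in CES1KD cells. Complement and Fc receptor genes had 9 of 14 lower and 3 higher (median -0.54, adjusted p = 0.00596), with the C1 inhibitor SERPING1 at -2.10 and C5AR1 at 2.85, but that call was lost (adjusted p = 0.0537 with an estimated correlation). The IL-4 list had 6 of 9 lower and 1 higher (median -0.38, adjusted p = 0.00596), TGM2 at -1.68, and scavenger receptors 6 of 7 higher and 1 lower (median 0.48, adjusted p = 0.0123), MSR1 at 1.29. With the estimated correlation those calls were lost (adjusted p = 0.0537 for IL-4 and adjusted p = 0.13 for scavenger receptors with an estimated correlation).

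Matrix genes rose in 16 of 19 and fell in 2 in M1 (median 1.75, adjusted p = 2.35e-08). Among them MMP8, a collagenase, went from 2.12 ± 0.521 to 29.9 ± 0.568 FPKM, and TIMP3 rose by 1.92. Cytokines and NF-kB targets rose in 9 of 13 and fell in 2 (median 0.67, adjusted p = 0.00732), IRAK2 by 1.77. NRF2 targets rose in 9 of 13 and fell in 1 (median 0.70, adjusted p = 0.000969), GCLC by 1.05, and heat shock genes in 8 of 10 with 1 lower (median 0.95, adjusted p = 0.00137), HSPA1A by 2.85. Immediate early genes rose in 9 of 11 and fell in 1 (median 0.76, adjusted p = 0.00284), FOS by 1.13, and histones rose in 6 of 7 (median 1.28, adjusted p = 0.000969). With the estimated correlation both were lost (adjusted p = 0.45 and adjusted p = 0.0518 with an estimated correlation). POU4F2, a transcription factor, rose by 3.58, the small heat shock protein HSPB7 by 3.27, the cancer-testis antigen MAGEB2 by 3.22, the hepatocyte growth factor receptor MET by 3.21 and TMEM158 by 3.06.

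Cell cycle genes fell in 20 of 23 in M1 (median -0.88, adjusted p = 2.35e-08), the replication clamp PCNA by 1.34. Granule genes fell in 7 of 8 and rose in 1 (median -3.03, adjusted p = 4.16e-05), PRTN3 by 3.53 and ELANE by 3.38. Monocyte markers fell in 7 of 8 (median -0.63, adjusted p = 0.000542), CX3CR1 by 2.09, and metallothioneins in 5 of 5 (median -2.48, adjusted p = 0.000151), MT1G by 2.52. Nuclear and mitochondrial genes of oxidative phosphorylation fell in 14 of 18 (2 rose, median -0.45, adjusted p = 0.00225) and in 9 of 13 (median -0.52, adjusted p = 0.025), ATP5F1A by 0.67 and MT-ND5 by 0.66. These calls were lost with the estimated correlation (adjusted p = 0.45 and adjusted p = 0.57 with an estimated correlation). AOC1, a diamine oxidase, fell by 3.83, the sorting receptor SORL1 by 3.83, CD9 by 3.70, TAC4 by 3.55 and PDLIM4 by 3.43. PDLIM4 lies within the shifted block of chromosome 5. Not called were hydrolases (9 higher and 6 lower of 20, adjusted p = 0.576), cholesterol synthesis (6 and 6 of 23, adjusted p = 0.933), LXR targets (2 and 3 of 11, adjusted p = 0.933) and PPARG targets (6 and 6 of 16, adjusted p = 0.576). Of the lipid genes, SQLE was at 1.35, ABCA1 at 1.46, PLIN2 at 2.19 and CES3 at -0.99. Adjusted over the list alone, the count in M1 was the same as over all genes for each list except 7. It was 16 for hydrolases (15 over all genes), 9 for eicosanoids (8), 19 for receptors (18), 12 for the stress response (11), 11 for NRF2 targets (10), 10 for mitochondrial genes (9) and 13 for complement (12). In M1 7578 genes passed the test, 3776 higher and 3802 lower, and 1027 of them differed at least 2-fold.

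In M2 cells, interferon and inflammatory genes were again higher in the knockdown cells, and several genes that IL-4 induces were lower. IFIT1 went from 1.32 ± 0.29 to 45.2 ± 4.99 FPKM and CXCL8 from 6.69 ± 0.789 to 92.3 ± 16.1 (SD, n = 4 each). FCER1A, a chain of the high-affinity IgE receptor, went from 82.4 ± 6.72 to 4.52 ± 0.962 FPKM, a log2 difference of -3.93 ± 0.09 (SE). F13A1, the A chain of coagulation factor XIII, went from 37.7 ± 1.49 to 3.35 ± 0.327 FPKM. SCIN, an actin-severing protein, went from 20.9 ± 0.354 to 0.909 ± 0.211 FPKM.

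All 26 type I interferon genes rose in M2 (median 2.54, adjusted p = 1.35e-25), MX1 by 3.86, RSAD2 by 3.56, ISG15 by 3.46, IFIT3 by 3.34 and OAS2 by 3.25, and SIGLEC1 rose by 3.52. Chemokines rose in 11 of 16 and fell in 4 (median 0.62, adjusted p = 0.00859), CXCL10 by 4.04 and CCL4 by 2.33. That call was lost with the estimated correlation (adjusted p = 0.0666 with an estimated correlation). Cytokines and NF-kB targets rose in 11 of 13 and fell in 2 (median 0.88, adjusted p = 0.000182), IL1B by 1.86 and BIRC3 by 1.44. The interferon gamma and MHC class I list had 13 of 21 higher and 2 lower (median 0.38, adjusted p = 0.000727), TAP1 at 1.25, and the stress response list 11 of 16 higher and 2 lower (median 0.41, adjusted p = 0.00244), DDIT3 at 1.60. Both were lost with the estimated correlation (adjusted p = 0.272 and adjusted p = 0.176 with an estimated correlation). The IL-4 list had 7 of 9 lower and 1 higher (median -0.32, adjusted p = 0.00432), with the lipoxygenase ALOX15 at -1.56 and CCL13 at -1.60, but adjusted p = 0.0555 with an estimated correlation. The prostaglandin synthase PTGS2 went from 4.77 ± 0.315 to 0.59 ± 0.153 FPKM, in an eicosanoid list with 3 higher and 7 lower of 13 (adjusted p = 0.111).

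Matrix genes rose in 16 of 19 and fell in 3 in M2 (median 0.83, adjusted p = 7.9e-07), MMP9 by 3.51 and MMP19 by 2.62. Heat shock genes rose in 7 of 10 and fell in 1 (median 0.72, adjusted p = 0.000888), DNAJB1 by 1.26, and NRF2 targets rose in 8 of 13 (median 0.50, adjusted p = 0.00107), ME1 by 1.13. Histones rose in 5 of 7 (median 1.40, adjusted p = 0.000318), HIST1H1C by 2.03, and immediate early genes in 8 of 11 (median 0.96, adjusted p = 0.000727), IER3 by 1.77. For immediate early genes the call was lost (adjusted p = 0.37 with an estimated correlation). Granule genes fell in 8 of 8 (median -3.18, adjusted p = 2.19e-07), PRTN3 by 4.18, CTSG by 3.72, ELANE by 3.66 and AZU1 by 3.6. CD9 fell by 4.49, TAC4 by 4.17, PDLIM4 by 3.66 and the protocadherin PCDHGA12 by 3.46, of which PDLIM4 and PCDHGA12 lie in the shifted block of chromosome 5. Monocyte markers fell in 7 of 8 (median -0.85, adjusted p = 0.000691), CCR2 by 2.24, and cell cycle genes in 22 of 23 (median -0.66, adjusted p = 2.19e-07), TYMS by 0.90. Metallothioneins fell in 5 of 5 (median -1.11, adjusted p = 0.00275), and nuclear and mitochondrial genes of oxidative phosphorylation in 14 of 18 (1 rose, median -0.48, adjusted p = 0.000888) and 13 of 13 (median -0.67, adjusted p = 0.001), NDUFA4 by 0.84 and MT-CO2 by 0.83. These calls were lost with the estimated correlation (adjusted p = 0.0643 for metallothioneins, adjusted p = 0.374 for the nuclear and adjusted p = 0.374 for the mitochondrial genes with an estimated correlation).

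Lipid lists had no call in M2: hydrolases had 5 higher and 6 lower of 20 (adjusted p = 0.715), cholesterol synthesis 7 and 7 of 23 (adjusted p = 0.899), LXR targets 3 and 2 of 11 (adjusted p = 0.599) and PPARG targets 8 and 4 of 16 (adjusted p = 0.434). Of these, ABCA1 was at 1.49, PLIN2 at 1.02, CES3 at -1.28 and LPL at 0.74. Adjusted over the list alone, the count in M2 was the same as over all genes for each list except retinoids (6, against 4 over all genes), heat shock (9, against 8) and histones (6, against 5). In M2 6929 genes passed the test, 3392 higher and 3537 lower, and 916 of them differed at least 2-fold. Within CES1KD M2, replicate 2 stood apart in how its residuals followed GC content across genes (rho -0.735, against 0.572 to 0.648 in the other 3), and without it 7385 genes were called in M2. Strong trends of both signs were also present in other groups. Replicates 3 and 4 had rho -0.64 and 0.682 in WT M1 and -0.615 and 0.647 in CES1KD M1. In WT M2, replicates 1 and 2 had 0.57 and -0.639.

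Across the 3 states, 2288 genes rose and 2236 fell in every one, of 9877 called in at least 1. Under the rule for named genes, which took protein-coding genes only, the largest rises common to the states were those of POU4F2 (3.08 in M0, 3.58 in M1 and 3.08 in M2), MAGEB2 (3.13, 3.22 and 2.93), NT5E, the ectonucleotidase CD73 (3.34, 2.88 and 2.65), MMP19 (2.98, 2.77 and 2.62) and HSPA1B (2.61, 3.02 and 2.81). ANKH, a pyrophosphate exporter within the raised block of chromosome 5, rose by 2.75, 2.58 and 2.67, and NR4A3 by 2.54, 3.82 and 2.89. The heat shock gene HSPA6 rose by 2.46, 2.99 and 2.92, the C5a receptor C5AR1 by 2.38, 2.85 and 2.50, and the collagen COL22A1 by 3.48, 2.37 and 2.6. Under the same rule, the largest falls common to the states were those of CD9, TAC4, PRTN3, ELANE and AZU1, followed by PDLIM4 (-3.05, -3.43 and -3.66), AOC1 (-2.98, -3.83 and -3.08), MLC1 (-3.61, -2.93 and -3.17), CTSG (-4.38, -2.89 and -3.72) and PLPPR3 (-3.90, -2.89 and -3.45). Lists of genes drawn independently would share fewer: M0 and M1 shared 2722 higher genes (1060 for independent lists) and 2498 lower (999), M0 and M2 2808 (952) and 2778 (929), and M1 and M2 2568 (967) and 2607 (1016). Opposite calls were 252 between M0 and M1, 52 between M0 and M2 and 223 between M1 and M2. Across genes, which are not independent replicates, the knockdown effects correlated at r = 0.75 between M0 and M1, 0.881 between M0 and M2 and 0.747 between M1 and M2. The same lines were compared in each state, so any other lasting difference between them would recur as well. Agreement between the states therefore cannot tell such a difference from an effect of the knockdown.

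The knockdown effect in M1 was set against that in M0 to ask which genes respond differently once LPS and interferon gamma are present. Among the gene lists, type I interferon genes, which were higher in the knockdown cells at rest, differed the most. IFIT1 differed between the states by -3.79 ± 0.15 (SE), CXCL10 by -4.21 ± 0.20 and the chemokine CCL1 by -3.82 ± 0.17. Opposite in direction was FABP4, which in M0 was 77.2 ± 6.08 in WT and 33.2 ± 1.49 FPKM in CES1KD cells, and in M1 18.6 ± 2.72 and 38.5 ± 2.71 (SD, n = 4 each). Its difference was 2.21 ± 0.14.

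Of the 26 type I interferon genes all 26 had a lower effect in M1 (median difference -2.44, adjusted p = 6.66e-46), among them IFI44L at -3.32, OAS2 at -3.29 and RSAD2 at -3.26. SIGLEC1 differed by -3.49 and C1QB by -3.39, the latter by -0.54 with voom (adjusted p = 0.773). The median level of these 26 genes was 4.64 FPKM in WT M0 and 37.5 in CES1KD M0, and 94.4 in WT M1 and 125 in CES1KD M1. The lower effect in M1 is thus one of ratios, since in FPKM the median level rose by a similar amount in both states. MHC class II was lower in 10 of 10 (median -1.82, adjusted p = 8.94e-19), HLA-DRA at -2.43, and the interferon gamma and MHC class I list in 18 of 21 (median -0.76, adjusted p = 2.03e-15). Levels of MHC class II genes near 0 in M0 limit that comparison: HLA-DRA went from 0.486 FPKM in WT M0 to 0.118 in CES1KD M0, and with voom its difference was -0.59 (adjusted p = 0.613). Chemokines differed with 9 lower and 4 higher of 16 (median -1.20, adjusted p = 0.000856), cytokines with 6 lower and 3 higher of 13 (median -0.24, adjusted p = 0.0184). Macrophage markers differed with 10 lower and 2 higher of 16 (median -0.37, adjusted p = 0.000856) and complement with 7 lower and 3 higher of 14 (median -0.30, adjusted p = 0.0011). Granule genes had 4 higher of 8 (median 0.55, adjusted p = 0.000734). With 0.1 added before log2 in place of 1, the calls of macrophage markers (adjusted p = 0.0632), complement (adjusted p = 0.199) and granule genes (adjusted p = 0.0838) were lost. Glycolysis genes had 11 lower of 23 (median -0.40, adjusted p = 1.64e-07) and cell cycle genes 12 lower and 2 higher of 23 (median -0.48, adjusted p = 0.000105), but both calls were lost (adjusted p = 0.0606 and adjusted p = 0.103 with an estimated correlation). Metallothioneins had 4 lower of 5 (median -0.69, adjusted p = 0.00415), immediate early genes 5 lower of 11 (median -0.53, adjusted p = 0.00572) and scavenger receptors 3 higher and 1 lower of 7 (median 0.24, adjusted p = 0.041). With the estimated correlation these 3 were lost (adjusted p = 0.0707 for metallothioneins, adjusted p = 0.496 for immediate early genes and adjusted p = 0.213 for scavenger receptors with an estimated correlation).

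Higher in M1 were also the differences of MMP8 (1.89), the adhesion molecule CEACAM6 (2.09), CD180, a relative of the toll-like receptors (2.02), SLC43A2 (1.83), PPP1R27 (1.82), TMEM37 (1.86) and EPB41L1 (1.82), of which CEACAM6 was not called with voom (adjusted p = 0.0546). Adjusted over the list alone, the count was the same as over all genes for the called lists except 6. It was 6 for scavenger receptors (4 over all genes), 5 for metallothioneins (4), 12 for glycolysis (11), 18 for cell cycle (14), 5 for granule genes (4) and 13 for macrophage markers (12). The effect differed in 3126 genes, 1372 higher and 1754 lower in M1, and 364 of the differences were at least 2-fold. Of the 3126, 43.9% were higher, against 54.1% with upper-quartile scaling.

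**Figure D4:**
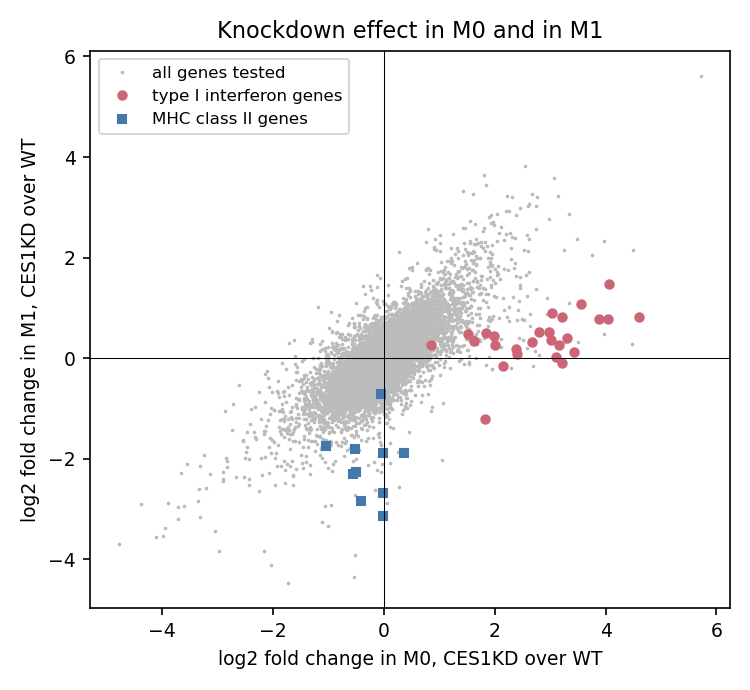
Log2 difference between CES1KD and WT cells in M0 (horizontal axis) and in M1 (vertical axis) for each gene tested, with type I interferon genes (circles) and MHC class II genes (squares) marked. Interferon genes had a median of 3.0 in M0 and 0.39 in M1, and MHC class II genes of -0.23 and -2.08.

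**Figure D5:**
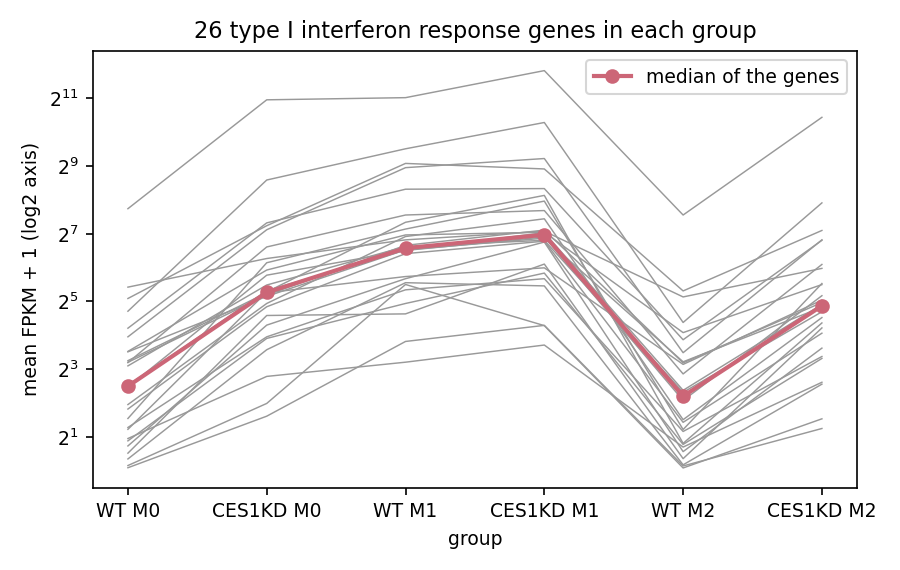
Mean FPKM plus 1 of the 26 type I interferon genes (grey lines) in the 6 groups on a log2 axis, with their median (circles). The median level was 4.64 FPKM in WT M0, 37.5 in CES1KD M0, 94.4 in WT M1, 125 in CES1KD M1, 3.59 in WT M2 and 28.3 in CES1KD M2.

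The knockdown effect in M2 was set against that in M0 in the same way, to ask which genes respond differently under IL-4. NTS, the precursor of neurotensin, was 11.9 ± 1.1 FPKM in WT M0 and 1.43 ± 0.523 in CES1KD M0, and 9.34 ± 0.811 in WT M2 and 22 ± 3.16 in CES1KD M2 (SD, n = 4 each), a difference of 3.58 ± 0.17 (SE). DHRS9 differed by 2.62 ± 0.15. FCER1A differed by -3.79 ± 0.13 and F13A1 by -2.54 ± 0.10, both induced by IL-4 in WT cells. The vascular adhesion molecule VCAM1 differed by -2.74 ± 0.13 and PTGS2 by -2.02 ± 0.13. The sign for F13A1 depends on the scale: its level in M0 was 0.562 FPKM in WT and 0.0108 in CES1KD cells, and with voom on the fragments, where no value of 1 FPKM is added, its difference was 2.335 (adjusted p = 0.0375). That of FCER1A was then -2.02 (adjusted p = 0.222).

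Among the lists, IL-4 response genes had 5 of 9 lower and 1 higher (median difference -0.46, adjusted p = 2.08e-05), chemokines 5 of 16 lower and 1 higher (median -0.45, adjusted p = 2.06e-05), and granule genes 3 of 8 higher (median 0.42, adjusted p = 0.00338, but adjusted p = 0.102 with 0.1 added before log2). Glycolysis genes had 11 of 23 lower and 1 higher (median -0.29, adjusted p = 6.26e-09), and type I interferon genes 6 of 26 lower (median -0.28, adjusted p = 4.92e-05), but both calls were lost (adjusted p = 0.064 and adjusted p = 0.264 with an estimated correlation). Immediate early genes had 5 of 11 lower (median -0.58, adjusted p = 1.26e-05) and cell cycle genes 1 of 23 lower (median -0.22, adjusted p = 0.00129), and both were lost (adjusted p = 0.22 each with an estimated correlation). Monocyte markers had 2 of 8 higher (median 0.19, adjusted p = 0.0331), PPARG targets 2 of 16 higher and 1 lower (median 0.07, adjusted p = 0.0335) and eicosanoids 4 of 13 lower and 1 higher (median -0.10, adjusted p = 0.0453). With the estimated correlation these 3 were lost (adjusted p = 0.0868 for monocyte markers and adjusted p = 0.22 for PPARG targets and eicosanoids with an estimated correlation). The differences of the collagen COL12A1 (2.02), the protease HTRA1 (1.92), the protease inhibitor SERPINE2 (1.72), the gap junction protein GJA1 (1.54), CEACAM6 (1.48) and the oncostatin M receptor OSMR (1.45) were higher in M2. With voom those of COL12A1 (0.92, adjusted p = 0.632), HTRA1 (1.24, adjusted p = 0.573), CEACAM6 (0.52, adjusted p = 0.849) and OSMR (0.35) were not called. Those of the lysyl oxidase LOX (-2.22), the amino acid oxidase IL4I1 (-2.09), CCL1 (-2.02) and FN1 (-1.90) were lower. Adjusted over the list alone, the counts were 7 for IL-4 genes, 12 for chemokines, 4 for granule genes, 18 for glycolysis and 8 for type I interferon. They were 6 for immediate early genes, 1 for cell cycle, 3 for monocyte markers, 5 for PPARG targets and 7 for eicosanoids. The effect differed in 881 genes, 319 higher and 562 lower in M2, and 93 of the differences were at least 2-fold. The count was 2086 with library weights and 1493 with GC and length trends removed, and 36.2% of the 881 were higher, against 48.4% after rescaling to TPM and 48.7% with upper-quartile scaling.

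The stimulations themselves, in WT cells, give the background of the knockdown effects. M1 stimulation took CXCL10 from 0.73 ± 0.351 to 1380 ± 63.4 FPKM and the chemokine CXCL9 from 0.0055 ± 0.011 to 250 ± 33.6 (SD, n = 4 each). CCL8 rose by 8.45, HLA-DRA by 8.20 and CCL1 by 7.78. LOXL4, a lysyl oxidase, fell by 2.29, the proprotein convertase PCSK6 by 2.28, CD180 by 2.24, TMEM37 by 2.22 and ATP6V1C2 by 2.19. The lists that rose were type I interferon (26 of 26, median 4.06, adjusted p = 5.67e-33), interferon gamma and MHC class I (21 of 21, median 2.25, adjusted p = 5.36e-23), chemokines (15 of 16, median 4.42, adjusted p = 1.18e-17), and MHC class II (10 of 10, median 3.48, adjusted p = 1.19e-15). Also higher were cytokines (11 of 13 and 2 lower, median 1.83, adjusted p = 7.44e-08), complement (12 of 14, median 1.07, adjusted p = 2.72e-09), macrophage markers (11 of 16 and 5 lower, median 1.06, adjusted p = 0.000212), metallothioneins (5 of 5, median 1.09, adjusted p = 0.000974) and cholesterol synthesis (14 of 23 and 1 lower, median 0.31, adjusted p = 0.00427). Cell cycle genes (19 of 23, median -0.63, adjusted p = 2.74e-09) and granule genes (7 of 8, median -0.73, adjusted p = 0.000223) fell. Calls lost with the estimated correlation were those of glycolysis (19 of 23 higher, adjusted p = 0.0617 with an estimated correlation) and immediate early genes (10 of 11 higher, adjusted p = 0.212). Lost as well were those of receptors and signalling (13 of 22 higher and 2 lower, adjusted p = 0.0775), matrix genes (9 of 19 higher and 5 lower, adjusted p = 0.139) and histones (5 of 7 higher, adjusted p = 0.193), each p with an estimated correlation.

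IL-4 took FCER1A from 0.107 ± 0.0986 to 82.4 ± 6.72 FPKM in WT cells and ALDH1A2, a retinal dehydrogenase, from 3.29 ± 0.152 to 101 ± 3.27 (SD, n = 4 each). F13A1 rose by 4.64, the lectin CD209 by 4.49 and the transglutaminase TGM2 by 4.36. CD14, the LPS co-receptor, went from 37.5 ± 4.13 to 2.06 ± 0.275 FPKM, and HTRA1 fell by 2.02, ALOX5AP by 1.88, C5AR2 by 1.77 and GPR82 by 1.75. IL-4 response genes rose in 9 of 9 (median 3.62, adjusted p = 2.99e-22) and matrix genes in 10 of 19 with 4 lower (median 0.26, adjusted p = 0.000122), while granule genes fell in 6 of 8 (median -0.54, adjusted p = 0.00021). Calls lost with the estimated correlation were those of glycolysis (18 of 23 higher and 1 lower, adjusted p = 0.0816), oxidative phosphorylation (8 of 18 higher, adjusted p = 0.499), immediate early genes (7 of 11 higher, adjusted p = 0.321) and heat shock (4 of 10 higher, adjusted p = 0.102). Lost as well were those of retinoids (4 of 8 higher and 1 lower, adjusted p = 0.0676) and PPARG targets (5 of 16 higher and 1 lower, adjusted p = 0.223). So were those of cell cycle (15 of 23 lower and 2 higher, adjusted p = 0.145), type I interferon (12 of 26 lower and 1 higher, adjusted p = 0.351), complement (9 of 14 lower and 1 higher, adjusted p = 0.0556) and MHC class II (4 of 10 lower, adjusted p = 0.427), each p with an estimated correlation.

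Adjusted over the list alone, the count for M1 stimulation was the same as over all genes for the called lists except receptors (16, against 15 over all genes), glycolysis (20, against 19), cell cycle (20, against 19) and matrix genes (15, against 14). For IL-4 the exceptions were PPARG targets (8, against 6), type I interferon (15, against 13), MHC class II (5, against 4), cell cycle (20, against 17), matrix genes (15, against 14) and immediate early genes (8, against 7). In WT cells 6374 genes passed the test for M1 against M0, 3493 higher and 2881 lower, and 3585 for M2 against M0, 1934 higher and 1651 lower. In CES1KD cells the counts were 5922 for M1, 3296 higher and 2626 lower, and 3025 for M2, 1500 higher and 1525 lower. The share higher depended on the scaling: for M1 in WT cells it was 54.8%, against 25.6% after rescaling to TPM, 32.7% with upper-quartile and 42.5% with quantile scaling. Rescaling to TPM moved the median of all genes by -0.24 in that comparison and upper-quartile scaling by -0.14. For M1 in CES1KD cells TPM moved it by -0.26, and the share higher went from 55.7% to 21.9%, with 39.1% under upper-quartile scaling. For M2 in WT cells 53.9% were higher, against 35.5% after rescaling to TPM and 40.7% with upper-quartile scaling. Of the called lists in the 7 comparisons, none had a median of the opposite sign under TPM, upper-quartile or quantile scaling.

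Some lists without a call had a median, a mean or a test of differing sign. They were hydrolases, LXR targets, lysosome, eicosanoids and retinoids for the knockdown in M0, cholesterol synthesis, LXR targets, retinoids and oxysterols in M1, and cholesterol synthesis, LXR targets, lysosome, retinoids and glycolysis in M2. For the difference between M1 and M0 they were NRF2 targets, mitochondrial genes and monocyte markers, and for that between M2 and M0 hydrolases, retinoids, heat shock and histones. For WT stimulation they were scavenger receptors and the IL-4 list in M1, and eicosanoids, cytokines and chemokines in M2.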

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

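The test of abundant transcripts from M1-stimulated cells, the test of M1 stimulation alone and the splits with the state effect removed were chosen after the result was seen.

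The knockdown effect differed between M1 and M0 in 3126 genes and between M2 and M0 in 881, each by a test of the difference itself. Of 100 splits of the same libraries into states within each line, the real one included, 2 gave as many genes as the 3126, with 5257 the highest of the others, and 2 gave as many as the 881, with 3069 the highest of the others. Such splits carry the effect of the stimulus itself into the difference, so they do not decide. With the state effect common to both lines removed, only 1 of 100 splits, the real one, gave as many, with 3132 genes and 1396 the highest of the others for M1, and 880 and 3 for M2. A random division of these libraries into states is thus an unlikely source of either count. A chance difference between the cultures of a line and state would follow the real groups, and these splits cannot test it. List medians that differed between M1 and M0 were -2.44 for type I interferon, -1.82 for MHC class II, -1.20 for chemokines, -0.76 for interferon gamma and MHC class I, -0.695 for metallothioneins, -0.53 for immediate early genes, -0.48 for cell cycle, -0.40 for glycolysis and hypoxia, -0.37 for macrophage markers, -0.30 for complement and Fc receptors, -0.24 for cytokines, 0.24 for scavenger receptors and 0.55 for granule genes. Of these, metallothioneins, immediate early genes, cell cycle, glycolysis and scavenger receptors were not called with an estimated correlation (adjusted p = 0.0606 to 0.496), and macrophage markers, complement and granule genes not with 0.1 added before log2 (adjusted p = 0.0632 to 0.199). Between M2 and M0 they were -0.58 for immediate early genes, -0.46 for the IL-4 response, -0.45 for chemokines, -0.29 for glycolysis and hypoxia, -0.28 for type I interferon, -0.22 for cell cycle, -0.10 for eicosanoids, 0.066 for PPARG targets, 0.19 for monocyte markers and 0.42 for granule genes. Of these, only the IL-4 response, chemokines and granule genes were called with an estimated correlation, where the others had adjusted p = 0.064 to 0.264, and granule genes were not called with 0.1 added (adjusted p = 0.102). Single protein-coding genes with the largest differences between M1 and M0 under the rule for named genes were CXCL10 (-4.21), CCL1 (-3.82), IFIT1 (-3.79), SIGLEC1 (-3.49), C1QB (-3.39, not called with voom), IFI44L (-3.32), OAS2 (-3.29) and RSAD2 (-3.26), and FABP4 (2.21), CEACAM6 (2.09, not called with voom), CD180 (2.02), MMP8 (1.89), TMEM37 (1.86), SLC43A2 (1.83), PPP1R27 (1.82) and EPB41L1 (1.82). Between M2 and M0 they were FCER1A (-3.79, not called with voom), VCAM1 (-2.74), F13A1 (-2.54, reversed with voom at 2.335), LOX (-2.22), IL4I1 (-2.09), PTGS2 (-2.02), CCL1 (-2.015) and FN1 (-1.90), and NTS (3.58), DHRS9 (2.62), COL12A1 (2.015), HTRA1 (1.92), SERPINE2 (1.72), GJA1 (1.54), CEACAM6 (1.48) and OSMR (1.446), of which COL12A1, HTRA1, CEACAM6 and OSMR were not called with voom. CEACAM6 and HTRA1 were at most 0.0878 FPKM in every CES1KD group, so their differences between states come from the WT level, which for CEACAM6 was 5.24 FPKM in M0, 0.457 in M1 and 1.19 in M2.

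Type I interferon genes were higher in the knockdown cells at rest by a median of 3.0 and in M1 by 0.39. With each library's trends with GC content and gene length removed, the median in M0 was 3.01, which argues against such a trend as the whole cause. RNA from M1-stimulated cells in the CES1KD M0 libraries could also raise them. For it the planned test found 20 other M1-induced genes in CES1KD M0 at a median of 7.83% of their CES1KD M1 level, against 29.9% for the interferon genes, which lay between the bounds set for it, and a form run first by mistake (40 genes, WT M0 level subtracted) gave 11.5 against 25.9%. These other genes were only required to be off the list and include SIGLEC1, which interferon also induces, so neither median decides. Of the same 20 genes, 8 had a share under 5.97%, the bound set from the interferon genes' median share, among them HLA-DRA (0.198%), CXCL13 (0.217%) and CCL8 (1.55%), which argues against cells that bring all their abundant transcripts. A candidate explanation of the smaller log2 effect in M1 is that the stimulus alone brought these genes above their level in resting knockdown cells. The list in WT M1 lay a median of 1.17 on the log2 scale above CES1KD M0. What raised these genes at rest was not tested, and an effect of the hairpin vector cannot be told apart from one of CES1 loss.

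Of 30 measures of libraries within a group, 3 had 1 library far from the other 3, and of 74 levels of named genes 6 did, where chance gives about 1 in 20. WT M0 replicate 2 held 22290832 fragments, against 14881563 to 15594964 in the other 3 libraries. CES1KD M2 replicate 2 had residuals that followed GC content at rho -0.735 (others 0.572 to 0.648) and gene length at rho 0.42 (others -0.366 to -0.287). CES1 was at 0 FPKM in CES1KD M0 replicate 2, against 0.103 to 0.116 in the others. In WT M0 replicate 4, FN1 was 2.18 FPKM (others 2.36 to 2.4), MMP9 66.1 (others 56.3 to 57.8) and CXCL9 0.022 (others 0). IFIT1 was 129 FPKM in WT M1 replicate 4 (others 144) and 0.886 in WT M2 replicate 1 (others 1.46 to 1.47).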

How the results depend on the processing

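The fits to protein-coding genes only, without the genes of the 4 chromosome blocks and with GC and length trends removed were chosen after the data were seen. A mean FPKM of at least 5 called 4245, 4513 and 4069 genes for the knockdown in M0, M1 and M2, 1977 and 549 for the differences of M1 and M2 from M0, 3755 and 2188 for M1 and M2 in WT cells and 3766 and 1944 in CES1KD cells, because fewer genes were tested, and CES1 itself was not tested there. The difference between M2 and M0 gave 2086 genes with library weights, where CES1KD M2 replicate 2 had a weight of 0.0846, and 1493 with GC and length trends removed. M2 stimulation in CES1KD cells gave 1861 in a fit to only the groups compared. For these 3 counts the cause was not tested. In a replicate block fit the counts were 7436, 7810 and 7203 for the knockdown in M0, M1 and M2, 3355 and 982 for the differences, 6608 and 3823 in WT cells, 6171 and 3219 in CES1KD cells, and 103 list calls. Of 15 pairs of groups, 0 had residuals correlated over 0.1 for every shared number. Between WT M2 and CES1KD M2 these correlations ran from -0.0578 to 0.41, with 3 over 0.1. The rho of residuals with GC content had the same sign by number in WT M1 (0.198, -0.251, -0.64 and 0.682) and CES1KD M1 (0.343, -0.3, -0.615 and 0.647). Whether the numbers pair the samples within M1 and M2 thus stays open. Without each library in turn the counts ranged over 6688 to 7963 for the knockdown in M0, 7155 to 8267 in M1, 6378 to 7385 in M2, 2791 to 3920 and 722 to 1178 for the differences of M1 and M2 from M0, 5869 to 7147 and 3007 to 4402 for M1 and M2 in WT cells, and 5411 to 6744 and 2585 to 3254 in CES1KD cells. The highest of each range was without CES1KD M2 replicate 2. CES1 ranged over -2.95 to -2.87 in M0, -2.49 to -2.35 in M1 and -2.84 to -2.75 in M2 without 1 library. Over the other settings it ranged from -7.07, -7.47 and -7.28 with voom, where no value of 1 FPKM is added, to -2.89 (library weights), -2.39 and -2.74 (trends removed). Protein-coding genes alone gave 6512, 6958 and 6306 calls in the 3 states, and trends removed 8100, 8383 and 7851. Genes at least 2-fold different in M0, M1 and M2 and in the differences of M1 and M2 from M0 were 642, 597, 546, 225 and 43 with a mean FPKM of at least 5, 1926, 1890, 1736, 680 and 168 with 0.1 added in place of 1, 1766, 1645, 1567, 617 and 164 after rescaling to TPM, and 2032, 1995, 1837, 687 and 177 with voom, against 1116, 1027, 916, 364 and 93.

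Of 251 named gene results, those lost under a setting (voom alone) all belonged to differences between states, and none was lost without 1 library. With voom F13A1 was reversed between M2 and M0 (2.335, adjusted p = 0.0375), and 8 were lost: C1QB (adjusted p = 0.773), HLA-DRA (adjusted p = 0.613) and CEACAM6 (adjusted p = 0.0546) between M1 and M0, and FCER1A (adjusted p = 0.222), COL12A1 (adjusted p = 0.632), HTRA1 (adjusted p = 0.573), CEACAM6 (adjusted p = 0.849) and OSMR (log2 difference 0.35) between M2 and M0. Levels near 0 in 1 state weigh more on that scale. List calls were 53 with the estimated correlation against 102 (every call lost is given with its p in the report), 104 with 0.1 added, 99 with upper-quartile scaling and 103 with trends removed. With 0.1 added 9 lists were gained, among them MHC class II in M0 (adjusted p = 0.0398), and 7 were lost, which were scavenger receptors (adjusted p = 0.0592), metallothioneins (adjusted p = 0.199), granule genes (adjusted p = 0.0838), macrophage markers (adjusted p = 0.0632) and complement (adjusted p = 0.199) between M1 and M0, and granule genes (adjusted p = 0.102) and monocyte markers (adjusted p = 0.182) between M2 and M0.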

Other observations

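The tests of copy number, of dividing cells and of granule genes on other chromosomes were chosen after the result was seen.

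A long noncoding RNA outside the rule for named genes, chosen after its values were seen, also differed between the lines. AC079466.1, on chromosome 19 from 28606688 to 28615229 in the coordinates of the deposited table, was 1.01 ± 0.261 FPKM in WT M0 and 104 ± 7.3 in CES1KD M0 (SD, n = 4 each). In M1 it was 0.727 ± 0.189 and 83.1 ± 4.68, and in M2 0.905 ± 0.224 and 115 ± 19.9. The log2 difference was 5.72 in M0, 5.61 in M1 and 5.92 in M2 (adjusted p = 3.6e-20, 8.07e-20 and 3.43e-20). CFD, the serine protease complement factor D, also chosen after its values were seen, fell by 2.67 in M0, 2.36 in M1 and 2.70 in M2.

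The metallothionein genes lie within 1 Mb of CES1 on chromosome 16. The 5 tested there had medians of -1.64, -2.48 and -1.11 in M0, M1 and M2, and the 9 other tested genes within 1 Mb -0.26, -0.24 and -0.13. Of those 9, LPCAT2, a lysophospholipid acyltransferase, fell by 1.35, 1.08 and 0.85, and the transcription factor IRX5 rose by 0.94, 0.90 and 0.85.

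Genes of 4 long blocks on chromosomes 1, 5 and 8 were shifted together between the lines, against a spread (SD) of 0.1 between the medians of all other windows of neighbouring genes in M0. The shift toward each block's direction was a median of 0.494 in M0, 0.495 in M1 and 0.496 in M2 over 781 genes. In the M2 libraries, which were not used to choose the blocks, it stayed at 0.496 with trends with GC content and length removed, which argues against such a trend. A candidate explanation is that the lines differ in copy number there: 86.7% of the block genes had the block's sign in M2, and the largest block median in any stimulation comparison was 0.149. Any lasting difference between the lines over these regions would give both values, so they do not single out copy number. Whether a copy number difference came with the knockdown, with the choice of cells or before it was not tested.

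Granule and progenitor genes had a median of -3.52 in M0, in a pattern present in all 3 states. Loss of a stretch of chromosome 19 could lower AZU1, PRTN3 and ELANE, and stays open for these 3. The 14 other tested genes within 200 kb had a median of -0.165, with 2 higher and 7 lower, but most of them lie outside a shorter stretch, and the nearest on each side fell (PLPPR3 by 3.90 and CFD by 2.67). The 5 tested list members on other chromosomes had a median of -2.258, 4 of them lower, which argues against that loss as the cause for them. Fewer undifferentiated dividing cells could lower progenitor genes. Cell cycle genes had a median of -0.42 in M0, 3.10 above that of the granule genes on the log2 scale. That argues against it as the whole cause only if cell cycle transcripts came mainly from such cells. If other cells held them too, a loss of the dividing cells could lower granule genes more, so the test does not decide. An effect of the knockdown on differentiation, and a difference between the lines from before it, stay open and were not tested.

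Splits of the 8 libraries of a comparison into other groups of 4 gave fewer genes than the real split in each knockdown and stimulation comparison. As large a count came from 1 of 35 splits, the real one, for the knockdown in M0 (7196, highest other 1), in M1 (7578, highest other 1) and in M2 (6929, highest other 3488). The same held, again with 1 of 35, for M1 stimulation in WT cells (6374, highest other 2) and in CES1KD cells (5922, highest other 2), and for M2 stimulation in WT cells (3585, highest other 1) and in CES1KD cells (3025, highest other 414). A share of 1 of 35 is the smallest that these splits can give, so a random division of the same libraries is an unlikely source of these counts. Such splits cannot test a chance difference between lines or cultures, which would follow the real groups.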
